A study of Caenorhabditis elegans with 2 samples.

How the data were processed

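Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Caenorhabditis elegans at the L3 larval stage, in animals of both sexes that carry a GFP-tagged copy of the nuclear receptor NHR-67, per the labels. The series held 2 biological replicates of 1 group and no second condition, so no comparison between conditions was made. The antibody is labelled only by the tagged protein's name, and the labels give a fragment size range of 150 to 350 bp. The aligner, the peak caller and their versions are not given in the sources used here.

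The authors deposited, for each of the genome builds ce10 and ce11, a list of candidate regions for each replicate, a list called on both replicates together, and a final list of peaks that passed their reproducibility (IDR) threshold, called optimal peaks from here on. Per the text records deposited with the samples, each list of candidate regions (the relaxed lists) was called against 1 control shared by both replicates, which was not analysed here, and the optimal list was derived from the pooled list and both replicate lists. In each list the authors gave a signal value, the caller's own enrichment against the control, and the −log10 of a q-value. The signal value is the authors' and differs in scale between lists, so its size was never compared between lists, and no mean and SD over replicates was taken. It served to describe, rank and filter regions within a list, to compare X with the autosomes and sum regions at the introduced loci within a list, and, as log2 values, to correlate the replicates across peaks. The deposited −log10 q was the same for every ce11 optimal peak, 3.14, and was not used to rank them. The p-value column of the deposited lists held only -1 and was not used.

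The files hold no read counts, so the sequencing depth of either replicate is unknown. Exact (Clopper-Pearson) 95% intervals on shares of peaks cover counting error over peaks only, and p-values over peaks describe these lists, since peaks are not independent replicates and there are 2 samples.

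The ce11 lists were used with the WBcel235 reference sequence and the Ensembl 115 annotation of the same assembly, and 0 regions ran past a chromosome end. The ce10 lists were used only for counts, shares, replicate overlap and signal correlation, and no coordinate was converted between builds. Coordinates are ce11 and 1-based. Each peak was assigned the protein-coding gene with the nearest annotated transcript start to its summit, and for the 3 lists of small RNA types the nearest start of any gene other than piRNA genes. Many C. elegans transcripts are trans-spliced, so an annotated start can lie downstream of where transcription begins, and where genes are transcribed away from each other the assignment is ambiguous. Mitochondrial gene names came from RefSeq. A summit was classed as promoter-proximal within 500 bp of a protein-coding start, and otherwise as exonic, intronic or intergenic.

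Lists of optimal peaks were compared with 10000 random draws of as many regions from the pooled relaxed list, which holds the regions that could have passed the authors' threshold. The smallest p these permutation tests can give is 0.0001 one-sided and 0.0002 two-sided. Replicate overlap was counted between the strongest regions of each replicate, as many as there were ce11 optimal peaks, sharing at least 1 bp, against 10000 random placements within chromosomes. Signal correlation across peaks used the strongest overlapping region in each replicate and 100000 permutations, which can give no p under 1e-05. Gene lists, 19 in number, were adjusted together by the Benjamini-Hochberg method. The half-site AAGTCA and all 2080 hexamers (reverse complements merged) were counted within 50 bp either side of each summit and compared by Fisher's exact test with relaxed regions that overlapped no optimal peak. Regions around nhr-67 and unc-119, of which the strain carries introduced copies, were compared with 10000 random autosomal windows of 40 kb.

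Tests, gene lists and alternatives were fixed before the data were examined. Named genes were those of the 25 optimal peaks with the highest signal, those of other peaks at members of a gene list that passed (at most 15), members of the anchor cell and uterine, ASE, RIA and GABA neuron, cell cycle and homeobox lists at any optimal peak (at most 20), nhr-67 and unc-119, and those of the 5 weakest peaks. Every other gene or peak named was chosen after its values were seen. Analyses restricted to nuclear regions, with nuclear relaxed regions as background, and comparisons of X with the autosomes were added after the mitochondrial peaks had been seen, and so was the correlation with each pair of matched regions counted once. Nuclear overlap was later also compared with 10000 draws from the nuclear relaxed list of each replicate.

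The alternatives were the ce10 lists, the stronger part of the optimal list, other overlap rules and list sizes, other distances to a start, random placements as background, other gene assignments, wider, flanking or GC-matched sequence windows, removal of the introduced loci, and the strongest regions of each replicate alone. The tests were checked on simulated data. A hexamer planted in 27 of 137 windows and a list planted at 10 of 137 regions were each recovered in 20 of 20 runs. Hexamers other than the planted one were also called in 20 of 20 runs (mean 2.85 per run), and other lists in 3 of 20. A list planted at fewer regions was not tried. The 30 planted overlaps were recovered in 20 of 20 runs, and without planting 0 of 20 runs of each test gave a call. Of 200 pairs of lists both drawn at random from the pooled nuclear relaxed regions, where the same region can be drawn for both, 17 (8.5%) gave an overlap call at 0.05, with at most 4 of 137 regions shared. These runs were made more numerous after a first version gave calls in some of them. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.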

Results

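NHR-67 is a nuclear receptor of the tailless family, known from work on the anchor cell, the uterus and several neuron types, and its binding was mapped in L3 larvae by ChIP-seq of the GFP-tagged protein. The series consisted of 2 biological replicates of this group, with 30000 relaxed regions in replicate 1 and 19385 in replicate 2 on ce11. The replicate 1 and pooled lists held exactly 30000 regions on both builds, so that number may be a limit on list size. The number of reads behind them is unknown. Both replicates together gave 137 optimal peaks on ce11 and 164 on ce10. Most ce11 optimal peaks, 107 of 137, were 256 bp wide, and the authors' signal value ran from 27.9 to 979 with a median of 38.2. The questions addressed were where the peaks lay, how well the replicates agreed, which genes lay nearest, and which sequences occurred at the summits.

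The strongest peaks lay on the mitochondrial genome. Of the 137 optimal peaks, 29 (21.2%, exact 95% interval 14.7 to 28.97) were mitochondrial, against 30 of the 30000 pooled relaxed regions. In random draws from the relaxed list the mean share was 0.105% (two-sided permutation p = 0.0002, the smallest possible, adjusted p = 0.0014 over 7 chromosomes). Their median signal was 234, and all 25 of the highest-signal peaks were mitochondrial. They were assigned to 11 of the 12 mitochondrial protein-coding genes, which encode subunits of the respiratory chain and ATP synthase. The highest signal, 979, had its summit at position 13160 of the mitochondrial genome, in an exon and 1469 bp from the start of ND5, a subunit of complex I. The next, 870, lay at position 4717, 213 bp from the start of CYTB, the cytochrome b gene of complex III. A further ND5 peak had a signal of 642 at position 12430, and a COX2 peak 332 at position 10376. The remaining peaks of the first 25 had signals from 111.9 to 306 and were assigned to ND1, ND2, ND3, ND4, ND4L, ATP6, COX1 and COX3 as well as to COX2 and ND5. Regions of the optimal list covered 11593 of the 13794 mitochondrial base pairs (84.0%). The mitochondrial peaks shared region bounds or lay close together, and merging regions within 200 bp left 6 mitochondrial regions and each nuclear peak apart.

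**Figure D1:**
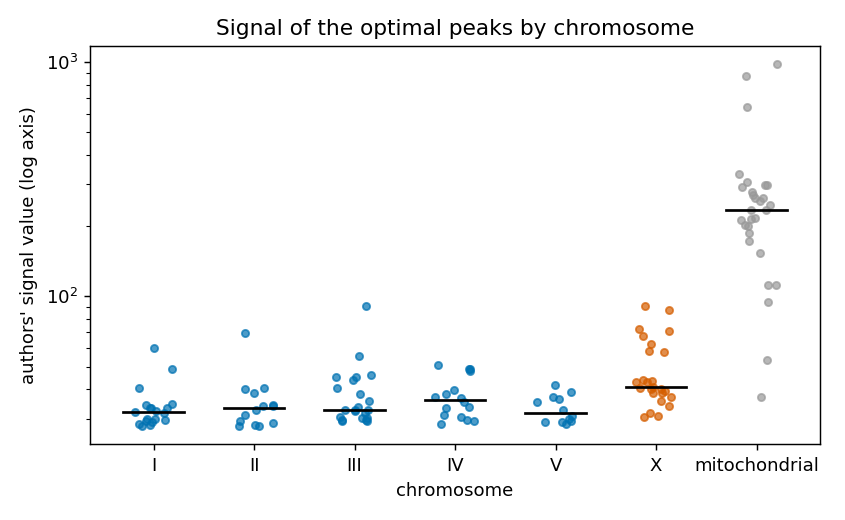
Signal value of each of the 137 optimal peaks (log axis) by chromosome, with black bars at the medians. The mitochondrial peaks have a median of 234, the X peaks 40.9, and the autosomes have medians from 31.7 (V) to 36.1 (IV).

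**Figure D2:**
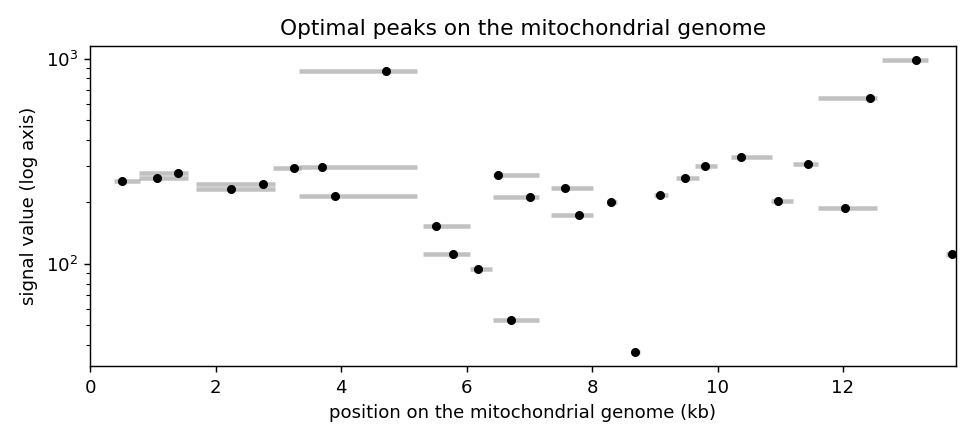
The 29 mitochondrial optimal peaks along the mitochondrial genome (kb), with each region drawn as a grey line and its summit as a black point at its signal value (log axis). The regions together cover 84.0% of the 13794 bp.

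Among the nuclear peaks, the strongest were sites on X away from gene starts and the start of a ribosomal protein gene. The X chromosome held 25 of them (23.1%, exact interval 15.6 to 32.2), chromosome III held 22, I held 19, IV held 16, II held 14 and V held 12. X supplied 7 of the 10 strongest nuclear peaks and 21 of the 54 strongest. The highest nuclear signal, 90.8, was at X 11094079 to 11094334, an intergenic region 3979 bp from the start of W02H3.3. Next on X came an intronic site of Y41G9A.17 at 2997034 to 2997289 (signal 87.6), and intergenic sites at 14525785 to 14526040 near nspc-17 (72.7), 16056571 to 16056669 near T27A8.7 (71.1) and 16681984 to 16682239 near F22H10.2 (67.5). On the autosomes the strongest were at III 3867440 to 3867695, 286 bp from the start of rpl-3, which encodes a protein of the large ribosomal subunit (90.6), and at II 10563440 to 10563695, 161 bp from the start of cdc-48.1, an AAA ATPase of protein degradation (69.8). These nuclear peaks were named after their values were seen.

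Over all 137 peaks the X share was 18.2%, against a mean of 17.6% in random draws from the relaxed list (two-sided permutation p = 0.91). With nuclear regions only the mean of the draws was 17.7% (permutation p = 0.171), so an excess of X peaks was not detectable in the whole list. In the 54 strongest nuclear peaks it was 38.9% against 17.7% (permutation p = 0.0006). In as many of the strongest nuclear regions of replicate 1 alone as there were nuclear peaks it was 29.6% (permutation p = 0.0038). In those of replicate 2 alone it was 28.7% (permutation p = 0.0132). These nuclear settings were chosen after the data were seen. The settings fixed beforehand kept mitochondrial regions and did not pass. There the X share was 27.5% in the 69 strongest peaks (permutation p = 0.0568). It was 23.4% in the strongest regions of replicate 1 alone (permutation p = 0.0972) and 22.6% in those of replicate 2 alone (permutation p = 0.248). Mean log2 signal was 5.53 ± 0.46 (SD over 25 peaks) on X and 5.13 ± 0.32 (SD over 83 peaks) on the autosomes, a difference of 0.40 (two-sided permutation p = 4e-05). Chromosome V held 8.76% of all optimal peaks against 18.5% in draws (permutation p = 0.0014, adjusted p = 0.0049), and with nuclear regions only 11.1% against 18.4% (permutation p = 0.0566, adjusted p = 0.34). The shares of I, II, III and IV over all peaks had adjusted permutation p of 0.931, 0.192, 0.934 and 0.192.

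The 2 replicates shared many of their strongest regions. Of the 137 strongest regions of replicate 1, 57 (41.6%, exact interval 33.3 to 50.3) overlapped 1 of the 137 strongest of replicate 2, against a mean of 25.5 in random placements (one-sided permutation p = 0.0001, the smallest these placements can give). The high chance value came from the mitochondrial genome, which held 29 of the regions in replicate 1 and 25 in replicate 2. With nuclear regions only 28 (25.9%, 17.97 to 35.2) were shared, against 0.0756 by placement (permutation p = 0.0001). Both replicates were called against the same control, which the random placements do not take into account. Across the 127 optimal peaks with a region in both replicates, log2 signal correlated with Spearman's rho = 0.51 and Pearson's r = 0.83 (both permutation p = 1e-05, the smallest possible, adjusted p = 2e-05 over 8 relations). Several mitochondrial peaks matched the same regions of both replicates, and with each of the 116 distinct pairs of regions counted once rho was 0.37 (permutation p = 6e-05) and r was 0.76 (permutation p = 1e-05). Across the 99 nuclear peaks rho was 0.02 (permutation p = 0.828, adjusted p = 0.828) and r was 0.11 (permutation p = 0.281, adjusted p = 0.281), so the relation over all peaks rested on the mitochondrial ones. Within the 28 mitochondrial peaks, which make 17 distinct pairs, rho was 0.40 (permutation p = 0.0347, adjusted p = 0.0556) and over those pairs 0.34 (permutation p = 0.178). Within the 25 X peaks rho was 0.27 (permutation p = 0.188, adjusted p = 0.214) and within the 74 autosomal peaks -0.20 (permutation p = 0.083, adjusted p = 0.111). These correlations are across peaks, which are not independent, and selection of peaks on the combined signal of these same replicates can lower them, so the nuclear values do not show that the order of signal differs. All 25 X peaks had a region in both replicates, while 9 of the 83 autosomal peaks had none in replicate 2. The median rank of the X peaks was 64 in replicate 1 and 57 in replicate 2, and that of the autosomal peaks was 110 and 331.5.

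**Figure D3:**
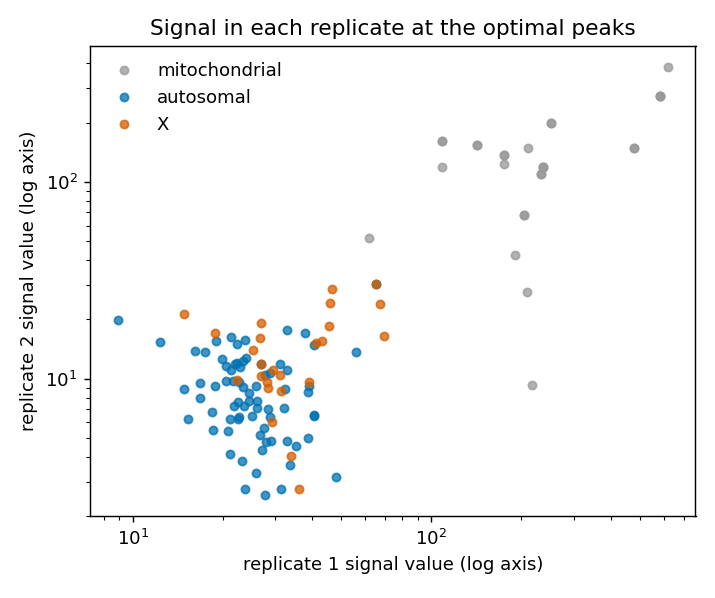
Signal value of the strongest overlapping region in replicate 1 (x axis) and replicate 2 (y axis), both log axes, for the 127 optimal peaks with a region in each. Mitochondrial peaks (grey) lie at the upper right, and within the nuclear peaks (blue autosomal, orange X) Spearman's rho is 0.02.

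Autosomal peaks lay at gene starts and X peaks did not. Of all optimal peaks 82 (59.9%, exact interval 51.1 to 68.1) had a summit within 500 bp of a protein-coding start, against 27.3% in draws from the relaxed list (one-sided permutation p = 0.0001). On the autosomes 59 of 83 did (71.1%, 60.1 to 80.5), against 28.5% (permutation p = 0.0001), with a median distance of 264 bp. On X 3 of 25 did (12%, 2.55 to 31.2), against 21.5% (permutation p = 0.932), with a median distance of 1652 bp. X and the autosomes differed from each other (Fisher's exact test, two-sided, p = 2.13e-07). The 3 X peaks at starts were those of bet-2, dpy-23 and puf-9. Of the other X summits, 14 were intergenic, 5 exonic and 3 intronic. At 24 of the 83 autosomal peaks a second gene also started within 500 bp, so the assigned gene is ambiguous there. On the mitochondrial genome, where genes lie end to end, 20 of 29 summits were within 500 bp of an annotated start, which says little about position.

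Ribosomal protein genes were over-represented among the nearest genes. No excess was detected for genes of the tissues in which NHR-67 is known to act. Peaks lay at 5 ribosomal protein genes (rpl-3, rpl-15, rpl-35, rps-12 and rps-28), 10.7 times the mean of 0.465 in draws (one-sided permutation p = 0.0001, adjusted p = 0.00095). The rpl-15 peak had a signal of 49.0, rps-12 45.4, rps-28 38.2 and rpl-35 32.6, with starts 145 to 425 bp away. In the strongest regions of replicate 2 alone the count was 1 against 0.526 (adjusted permutation p = 1), so this result rests on replicate 1, where it was 4 against 0.445 (adjusted permutation p = 0.0124). tRNA genes were nearest to 13 peaks against 1.74 (permutation p = 0.0001, adjusted p = 0.00095), of which 10 were mitochondrial. With nuclear regions only the tRNA count was 3 against 1.31 (adjusted permutation p = 0.681), and random placements within chromosomes gave 12.4 (adjusted permutation p = 1), so the excess reflected the mitochondrial peaks. These 3 lay on X, in or near W02H3.3, R11.4 (signal 40.9) and M02F4.2 (30.7). The mitochondrial tRNA peaks outside the first 25 were assigned to ND4 (94.6) and COX1 (37.2) among protein-coding genes.

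Translation factors and chaperones had 3 peaks, at eef-1G, hsp-1 and hsp-90, against 0.467 (permutation p = 0.0118, adjusted p = 0.056), and small nuclear and nucleolar RNA genes 6 against 1.75 (permutation p = 0.009, adjusted p = 0.056). Both lists changed sides with the setting. Both passed against random placements (adjusted permutation p = 0.0152 and 0.0124), with starts within 1000 bp (0.0184 and 0.0252) and, in a setting chosen after the data were seen, with nuclear regions only (0.0443 and 0.0228). The second also passed without replicate 2 (adjusted permutation p = 0.038). Among the 69 strongest peaks the first had 0 against 0.247 and the second 3 against 0.885 (adjusted permutation p = 1 and 0.376), and without replicate 1 they had 1 and 4 (adjusted permutation p = 1 and 0.763). By the nearest start of any gene the first had 2 (adjusted permutation p = 0.282). No optimal peak was assigned to the anchor cell and uterine list (0 against 0.566), the vulval and signalling list (0 against 0.466), the ASE, RIA and GABA neuron list (0 against 0.242), the cell cycle list (0 against 0.297), the homeobox list (0 against 1.15), the nuclear hormone receptors (0 against 2.38) or the histones (0 against 0.12). These counts take only the nearest start. A second start within 500 bp belonged to lin-7, of the vulval and signalling list, at the elof-1 peak. The same held for rpl-20 at the Y17G9B.5 peak and the chaperone gene cct-8 at the Y55F3AR.2 peak. Among markers of cell types, the pan-neuronal (0.439 by chance), muscle (0.541), intestine (0.221) and pharynx and gland (0.175) lists had 0 peaks each. The hypodermis, seam and cuticle list had 1 peak, at col-94, against 1.71, and the germline list 1, at puf-9, against 0.291. The basic helix-loop-helix list had 1, at mxl-3, against 0.448, and the microRNA genes 1, at mir-52, against 0.87. The adjusted permutation p of these 15 lists ran from 0.967 to 1. A count of 0 among 137 peaks leaves an exact upper limit of 2.66%. That lies above the chance share of each of the lists with 0 peaks, so lower counts than chance were not detectable. Whole larvae were used, and binding confined to a few cells could go undetected. These counts therefore do not show that NHR-67 is absent from such genes.

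**Figure D4:**
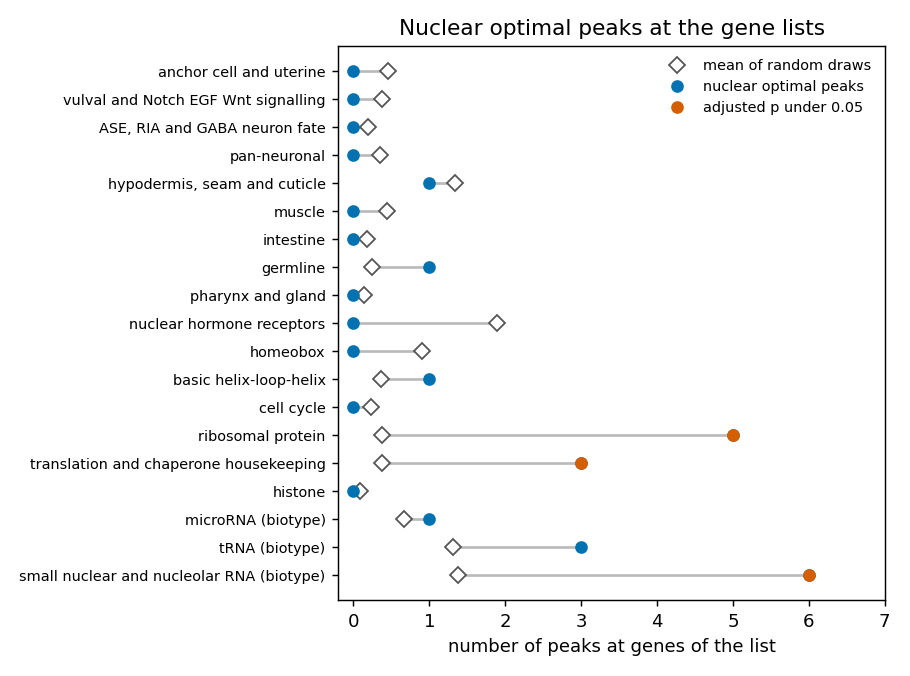
Number of the nuclear optimal peaks assigned to each of 19 gene lists (filled points) and the mean of 10000 random draws from the nuclear relaxed regions (open diamonds). Orange points have an adjusted permutation p under 0.05: ribosomal protein (5 peaks), translation and chaperone (3) and small nuclear and nucleolar RNA (6).

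The 5 weakest optimal peaks were at ubr-4 (signal 28.3, 330 bp from its start), myrf-1 (28.1, 384 bp), lin-28, a regulator of larval developmental timing (27.9, 612 bp), F53A10.2 (27.9, 345 bp) and din-1 (27.9, 3994 bp).

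The sequence AAGTCA, the site recognised by the receptor family of NHR-67, was no more frequent at the peaks than elsewhere. It lay within 50 bp of 5 of 137 summits (3.65%, exact interval 1.20 to 8.31), against 4.36% of 29857 relaxed regions (Fisher's exact test, one-sided, p = 0.718). On X it was at 2 of 25 summits and on the autosomes at 2 of 83 (2.41%). Other hexamers did differ. Of 2080 tested, 116 passed an adjusted p of 0.05 by Fisher's exact test, 99 more frequent at summits and 17 less frequent. Windows at summits were richer in G and C, at 40.5% against 35.2%, and against background windows of like GC content 39 hexamers passed, all more frequent at summits. The count was 67 against flanking windows, 176 with nuclear regions only, and 39 without replicate 1. CGCGCA had the lowest p, with 25 of 137 summits (18.2%) against 1.79% of background windows (Fisher's exact adjusted p = 1.65e-14) and 2.92% of GC-matched windows (adjusted p = 7.02e-08). Without replicate 1 it was at 15 of 137 summits (10.9%, Fisher's exact adjusted p = 2.28e-05), and CTGCGC had the lowest p. Among the optimal peaks CGCGCA occurred at 9 of 25 X summits and 16 of 83 autosomal summits. On X alone the lowest p belonged to CCCTGC, at 11 of 25 summits (44.0%) against 1.31% of X relaxed regions (Fisher's exact adjusted p = 3.78e-11), followed by CCTGCG and CTGCGC at 10 each. On the autosomes alone CGCACA had the lowest p, at 18 of 83 summits (21.7%) against 2.21% (Fisher's exact adjusted p = 8.35e-10). Summit windows were richer in G and C than background on X (43.1% against 35.6%) and on the autosomes (46.2% against 35.1%). The GC-matched background was used only for all 137 peaks together, so the results for X and the autosomes are not corrected for GC content. Mitochondrial windows were among the 137, and the nuclear windows alone had a GC content of 45.5%. Part of the 39 hexamers can therefore reflect mitochondrial sequence, and nuclear peaks were not tested against a GC-matched background.

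The nhr-67 locus itself gave little signal. Within 20 kb of the nhr-67 start (IV 11169748) the pooled relaxed list held 1 region, against 11.9 ± 4.59 (SD over windows) in random autosomal windows (one-sided permutation p for more = 0.996). That region ranked 22221 of 30000 by signal. Replicate 1 held 2 regions against 11.95 and replicate 2 held 1 against 7.63. Their summed signal was 12.1 in replicate 1 against a mean of 86.2, and 2.52 in replicate 2 against 27.9. Around the unc-119 start (III 10902641), a gene for nervous system function used as the transgene marker, there were 16 regions (permutation p for more = 0.207), 17 in replicate 1 and 8 in replicate 2, and no optimal peak lay within 20 kb of either start.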

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

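Settings restricted to nuclear regions or to distinct pairs of regions were chosen after the data were seen, and all others before. Replicate overlap passed under every alternative run, and draws from the relaxed list of each replicate gave a mean of 0.0966 shared nuclear regions. The promoter-proximal share passed in every setting except X alone (12% against 21.5%, one-sided permutation p = 0.932). The low share of chromosome V did not pass with nuclear regions only (adjusted permutation p = 0.34). The Spearman correlation of replicate signal fell to 0.022 with nuclear regions only. The X share was 16.5% on ce10, below its random mean of 17.7%, and the AAGTCA share of 3.65% lay above the 3.58% of GC-matched background. Neither of these had passed. The X share did pass among the 54 strongest nuclear peaks and in nuclear regions of each replicate alone. It did not pass in the corresponding settings fixed beforehand, which kept the mitochondrial regions. Keeping the stronger part of the list left 69 optimal peaks, a number that the setting itself fixes. Gene lists that passed numbered 2, 1 by Fisher's test over all protein-coding genes, and 4 with starts within 1000 bp, and the strongest regions of single replicates gave 1 to 3. Only 16 lists entered Fisher's test, without the 3 lists of small RNA types, so the tRNA list could not pass there. The ribosomal protein list still passed (Fisher's exact adjusted p = 0.00185). Fewer regions entered some other settings, and the cause of the other differences was not tested further. Hexamers that passed numbered 67 against flanking windows, 39 against GC-matched windows and 176 with nuclear regions only, and 39 to 86 in single replicates. The ribosomal protein list did not pass without replicate 1, and the tRNA list did not pass against random placements or with nuclear regions only. The translation and chaperone list and the small nuclear and nucleolar RNA list passed in 4 alternative settings, the first in 3 of them, and both also passed on the autosomes alone. In 5 settings, lists with no call crossed their chance value, 10 times in all, with counts of 0, 1, 2 or 3 peaks. No paired analysis was possible because there was 1 group. The unknown depth of the replicates limits what absent peaks can show.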

Other observations

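The tests of mitochondrial coverage, of X copy number and of ribosomal protein genes were chosen after the results they measure had been seen, as was the lower-tail test at nhr-67. The sequence element was chosen because the positions of the strongest X peaks seemed to resemble known recruitment sites, before their sequence was read. That resemblance was not tested, and the element was not chosen independently of these peaks.

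The element GCGCAGGGAG, described for sites where the dosage compensation complex is recruited to X, occurred with at most 1 mismatch in 11 of 25 X optimal regions (44.0%, exact 95% interval 24.4 to 65.1). It was in 22 of 5248 X relaxed regions (0.419%, Fisher's exact p = 3.76e-19) and in 0 of 83 autosomal optimal regions (Fisher's exact p = 1.29e-08), an upper limit of 4.35%. The exact sequence was in 3 X optimal regions, at X 11094123 to 11094132, X 2997121 to 2997130 and X 5429590 to 5429599, and in 3 of the X relaxed regions. With 2 mismatches allowed it was in 16 of 25 X optimal regions, and also in 11 of 83 autosomal optimal regions (13.3%), against 6.75% of autosomal relaxed regions (Fisher's exact p = 0.0241). The 11 X peaks with at most 1 mismatch had a median signal of 62.2 (39.96 to 90.8), and 0 lay within 500 bp of a start. The 14 other X peaks had a median of 38.6 (30.5 to 57.9), and 3 lay that close. CCCTGC, CCTGCG and CTGCGC, the hexamers with the lowest p on X, are reverse complements of parts of the element.

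A candidate explanation for the X peaks with the element, 44.0% of them, is recovery of dosage compensation complex recruitment sites in this ChIP. AAGTCA was at 8% of X summits, with an upper exact limit of 26.0%, which argues against direct binding at that site as the cause for most of them. The share of X regions made mostly of repeated 36-mers was 0%, with an upper limit of 13.7%, which argues against reads of several loci. The X share of nuclear relaxed regions was 17.6% (17.2 to 18.04), no higher than the 17.7% X share of the nuclear genome. Regions were called against a control, so their share does not measure the amount of X DNA. The 17.6% lay within the exact interval of 15.6 to 32.2 for all nuclear optimal peaks. No X excess was detectable in that whole list, so this comparison cannot exclude more X DNA. For the 54 strongest nuclear peaks alone the interval was 25.9 to 53.1, above the relaxed share. The X excess had been found in that subset, so this does not decide the question either. Whether NHR-67 is present at these sites or they are recovered whatever protein is tagged stays open, since no other tagged protein was analysed here.

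Abundant mitochondrial DNA recovered without site preference could not be tested as a source of the mitochondrial peaks. Relaxed regions covered 71.5% of the mitochondrial genome in the replicate with less coverage, but the wide coverage prompted this explanation and so cannot support it. Signal was uneven, from 37.2 to 979, and the ND5 and CYTB peaks with the highest signal matched the 2 strongest regions of each replicate. AAGTCA was at 3.45% of the 29 summits, with an upper exact limit of 17.8%, against 2.09% of all mitochondrial positions, which argues against binding at that site. The control library was not analysed here.

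For the autosomal peaks, many of them at gene starts, non-specific recovery at highly transcribed genes could not be tested, since no expression data were analysed. The 5 nuclear peaks at ribosomal protein genes prompted this explanation and so cannot support it, and they are few among 83 autosomal peaks. AAGTCA was at 2.41% of autosomal summits, with an upper exact limit of 8.43%, and 1.21% of autosomal regions (upper limit 6.53%) were mostly repeated 36-mers, which argues against both as the cause for most of these peaks. Other sequences were more frequent at autosomal summits (124 of 2080 hexamers). The autosomal windows were richer in G and C (46.2% against 35.1%), and no GC-matched background was used for them. Whether NHR-67 binds there through any of these sequences or through a partner stays open.

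The 1 relaxed region within 20 kb of the nhr-67 start was fewer than in most random autosomal windows (permutation p for fewer = 0.0095). The strain carries introduced copies of this gene. Regions were called against a control that was not analysed here, so the count cannot be read as copy number.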
